A study of Arabidopsis thaliana with 6 samples.

How the data were processed

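Gene expression was measured in whole seedlings of Arabidopsis thaliana with Affymetrix ATH1 arrays, per the labels' protocols. Seedlings 10 days old were kept in air-purged water for 6 h as a low-oxygen stress and then recovered on agar medium for 22 h before total RNA was extracted. All 6 arrays came from treated seedlings, 3 of the wild-type accession Wassilevskija and 3 of the atr8 mutant, so the effect of the stress itself was not analysed here. The series describes the arrays of each genotype as biological replicates. Biotin-labelled cRNA was made from total RNA by the standard Affymetrix protocol, per the labels' protocols.

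The deposited values were intensities on a linear scale, 1 per probe set and array, from 1 to 47944 with a median of 192.9 on each array. All 6 columns held the same sorted values within a tolerance of 0.02, so the deposited intensities had been quantile normalized across the arrays. The software that summarized probes into probe sets, its version and any background correction are not given in the sources used here. Scanner files were not used here, and no detection call stood beside the values. The number of arrays limits the precision.

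Of 22810 probe sets, 64 control probe sets were left out of the tests and 22746 were tested. The platform annotation listed 13513 probe sets with 1 gene and 503 with several genes. The 8730 probe sets it did not list are unnamed here, not without a gene. Of the probe sets with 1 gene, 13436 matched a current locus in the RefSeq gene table of assembly TAIR10.1, which served only for names and for gene order. Together these probe sets named 13355 genes, 1557 of them by a symbol and the others by locus. Of several probe sets naming only the same gene, the brightest over all 6 arrays stood for the gene in gene lists.

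Values were transformed to log2(intensity + 16) and the mutant was compared with the wild type by lmFit and eBayes of limma 3.58.1 in R 4.3.3, with genotype as the only term. P-values were adjusted by the Benjamini-Hochberg method over all tested probe sets, with a threshold of 0.05. A difference on this scale understates the change of dim genes. Gene lists were tested with limma's camera, two-sided, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 11 lists with at least 2 measured members. The camera tests were repeated with a correlation estimated from the data. This option also takes the residual degrees of freedom of the fit, far fewer than with a preset correlation, and that alone raises p. A loss of the threshold there is thus no evidence of correlation between genes.

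The gene lists, the design and the rule for named genes were fixed before the data were examined. A list member was kept only where its locus and a written symbol matched in the annotation, which left out 9 measured loci. Members without a probe set naming them alone were not tested either, so each list rests on a small part of its genes. The rule named any probe set of AtR8, the 12 genes with the largest rise and the 12 with the largest fall among genes past the threshold whose 3 mutant arrays all lay beyond the wild-type arrays. From each list it named at most 4 members past the threshold over all probe sets or over the list alone, or otherwise the 2 with the smallest p. It also named PR1, WRKY53, WRKY70, NPR1 and ADH1, of which only WRKY53 had a probe set with a single gene in the annotation used. Genes outside this rule are marked where they appear as chosen after their values were seen.

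Alternatives planned beforehand were the replicate number as a block, quantile normalization, median centring, removal of the dimmest 30 percent of probe sets, an intensity trend with a robust prior, array weights, pseudocounts of 1 and 64, each array left out in turn, an estimated inter-gene correlation, and the mean of all probe sets of a gene. Chosen after seeing the data were cyclic loess normalization, a term for mutant replicates 2 and 3, mutant replicate 1 alone against the wild type, and list members taken by locus alone.

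The limma test was tested on simulated data of the same size, with 22746 probe sets in 5 simulations. It called 0.80% of simulated 2-fold changes, 38.4% of 4-fold, 54.0% of 8-fold and 68.8% of 16-fold changes between 3 and 3 arrays, and 6.03% of its calls were false. A simulated 2-fold shift of the photosynthesis list was called by camera in 20 of 20 simulations, and 6 of 200 unshifted lists had an unadjusted p under 0.05. In both simulations genes were drawn independently of each other and all arrays were alike in quality. In the limma simulation 250 probe sets were changed at each fold over all 5 simulations, and simulated values could fall below the lowest intensity of the arrays. These rates therefore do not cover correlated genes, arrays that differ in labelling, falls limited by the lowest intensity, or another share of changed probe sets.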

Results

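The series addressed the role of AtR8, a long non-coding RNA of Arabidopsis, in defence responses. Transcript levels were measured in 3 arrays of wild-type seedlings and 3 arrays of atr8 mutant seedlings, all sampled after 6 h of low-oxygen stress and 22 h of recovery. No probe set was named for AtR8 in the annotation used, so the level of the mutated gene itself was not analysed here. Between arrays, log2 intensities correlated across probe sets at 0.905 to 0.924 within the wild type and at 0.902 to 0.919 within the mutant. Between the genotypes these correlations lay from 0.872 to 0.909. Mutant replicate 1 correlated at 0.902 and 0.908 with mutant replicates 2 and 3. With wild-type replicates 1, 2 and 3 it correlated at 0.891, 0.907 and 0.909.

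The comparison of mutant with wild type asked how transcript levels differ between the genotypes in stressed and recovering seedlings. WRKY53, a transcription factor of leaf senescence and pathogen defence, rose 7.55-fold in the mutant (log2 difference 2.92 ± 0.23, SE, n = 3 arrays per genotype, adjusted p = 0.0233 by limma). The class III peroxidase PRX52 rose 22.1-fold and the high-affinity nitrate transporter NRT2.5 rose 14.7-fold, where folds are of the intensity + 16. Both lost the threshold with 1 added in place of 16 and without mutant replicate 1. All 3 genes lost it with the replicate number as a block and without any one of the other 5 arrays, where adjusted p-values of WRKY53 were 0.237 and 0.0871 to 0.135. AT1G26390 and AT1G26410, which encode berberine bridge enzyme-like oxidoreductases, also rose. Of nuclear photosynthesis genes 6 of 38 listed were measured, and of abscisic acid, cold and drought genes 4 of 26. Both groups stood lower with a preset inter-gene correlation and did not pass with an estimated one. Mutant replicates 2 and 3 had lost 5′ signal in control probe sets.

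In all, 209 probe sets (0.919% of those tested) differed at an adjusted p under 0.05, 162 higher and 47 lower in the mutant. All 209 differed at least 2-fold, the smallest by 1.23 on the log2 scale. At an unadjusted p under 0.05 there were 3190 probe sets, where 1137 were expected by chance. Of the 209, 108 named a single gene, 83 of them higher and 25 lower. The other 101 were left out when genes were ranked by rise and fall below.

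With 16 added to the intensities, the largest rise was that of AT3G18250, by 4.57 ± 0.41 on the log2 scale, from an intensity of 73.3 ± 37.8 (SD, n = 3) in the wild type to 1996 ± 451 in the mutant. PRX52 followed with 4.47 ± 0.51, from 56.0 ± 41.5 to 1372 ± 153. AT5G22555 rose by 4.09 ± 0.24, NRT2.5 by 3.88 ± 0.50 and AT1G26390 by 3.78 ± 0.36. AT1G56060 rose by 3.50 ± 0.24 and AT1G26410 by 3.31 ± 0.26. The wild-type means of both, of AT5G22555 (11.9) and of ndhF (8.32) lay under 16, where the size of a rise depends on the value added. With 1 added in place of 16, AT1G26410 rose by 5.44, AT5G22555 by 5.17, PRX52 by 4.98 and AT1G56060 by 4.96, all by more than AT3G18250, and with 64 added AT1G26410 rose by 1.82, PRX52 by 3.64 and NRT2.5 by 2.83. With 1 added PRX52, NRT2.5 and ndhF lost the threshold (adjusted p = 0.0782, 0.0952 and 0.057), as did PRX52 and NRT2.5 without mutant replicate 1 (0.0564 and 0.062). AT2G17740 rose by 3.13 ± 0.26 from a higher wild-type level of 311 ± 88.0 to 2800 ± 382. The last 4 of the 12 were ndhF, a chloroplast-encoded subunit of the NADH dehydrogenase-like complex, at 3.02 ± 0.37, AT5G52760 at 3.00 ± 0.32, AT1G49030 at 2.98 ± 0.28 and AT1G72060 at 2.97 ± 0.29. Adjusted p-values of the 12 lay between 0.0233 and 0.0388.

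The genes with the largest falls were dim, and the order and size of the falls depend on the 16 added. AT5G40140, a U-box protein gene, fell by 2.55 ± 0.24 on the log2 scale, from an intensity of 116 ± 18.0 in the wild type to 6.84 ± 5.21 in the mutant. TRM24 followed at −2.43 ± 0.25 and AT2G02650 at −2.40 ± 0.31. The log2 difference was −2.31 ± 0.31 for AT3G48030, −2.26 ± 0.28 for AT5G50140, −2.23 ± 0.21 for AT1G51320 and −2.22 ± 0.20 for AT2G04063. For AT3G50290 it was −2.06 ± 0.23, for the pectin methylesterase gene AT5G49180 −2.04 ± 0.25, for AT3G60700 −2.02 ± 0.19 and for AT2G04300 −1.90 ± 0.21. AT3G26860 fell from an intensity of 70.0 ± 7.12 to 4.13 ± 2.13. Adjusted p-values of the 12 lay between 0.0233 and 0.0391. With an intensity trend and a robust prior 10 of the 12 lost the threshold (adjusted p = 0.0539 to 0.137), all but AT5G40140 and TRM24. With 1 added in place of 16, 6 of the 12 lost it (0.0529 to 0.0632), AT5G40140 among them, and TRM24 fell more (−4.32) than AT5G40140 (−4.09), which fell by 1.34 with 64 added. Of the 12, 0 were tested once the dimmest 30% of probe sets were left out. Across all 47 lower calls the median intensity was 96.5 in the wild type and 7.75 in the mutant, and 35 of them had a mutant mean under 16. Across the 162 higher calls the medians were 215 and 982, and 40 of them had a wild-type mean under 16.

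**Figure D1:**
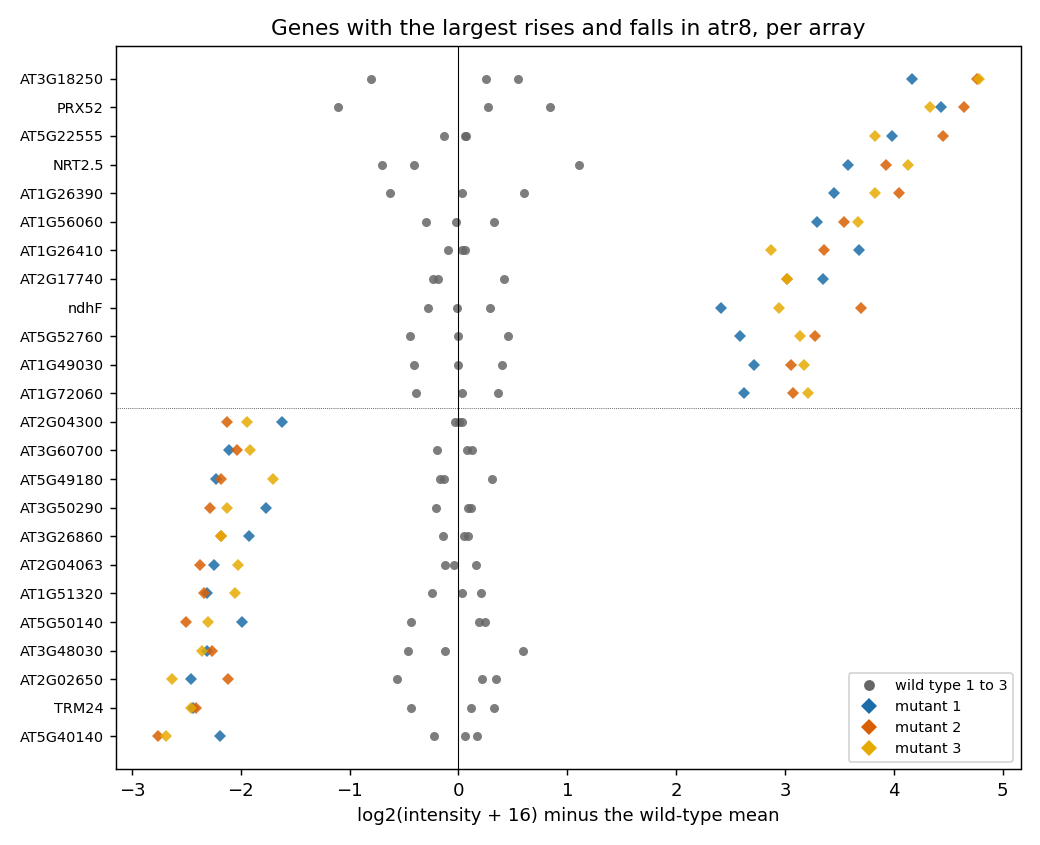
Each row is a gene and each point an array, placed by its log2(intensity + 16) minus the mean of the 3 wild-type arrays (grey circles); diamonds are the 3 mutant arrays. Ranked among genes that a changed probe set names alone, the upper 12 had the largest rises, up to 4.57 for AT3G18250. The lower 12 had the largest falls, down to −2.55 for AT5G40140.

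Lists of pattern-triggered immunity, salicylic acid and WRKY factors stood higher with a preset correlation, and none of them passed with an estimated one. Of their listed genes 4 of 25, 2 of 29 and 7 of 72 were measured, so these results cover a small part of each list. In the list of pattern-triggered immunity and camalexin, all 4 measured members had higher estimates, with a median log2 difference of 1.28 (camera adjusted p = 0.000158; adjusted p = 0.0726 with an estimated correlation). WRKY53 was the only member past the threshold over all probe sets, and 2 members rose when adjusted over the list alone. The second was BIK1, a receptor-like cytoplasmic kinase, with 1.04 ± 0.22 on the log2 scale and an adjusted p of 0.0062 over the list. In the salicylic acid list both measured members were higher and 2 rose adjusted over the list alone, against 0 over all probe sets (camera adjusted p = 0.013; adjusted p = 0.111 with an estimated correlation). These were GRX480, a glutaredoxin induced by salicylic acid, at 1.52 ± 0.29 and SAG101, a partner of EDS1, at 0.88 ± 0.35. For SAG101 the limma adjusted p was 0.0463 over its list of 2 and 0.348 over all probe sets, and its mutant and wild-type arrays overlapped. The salicylic acid list did not pass without mutant replicate 1 (camera adjusted p = 0.0559). Among WRKY factors, 5 of 7 measured members had higher estimates, 1 rose over all probe sets and 2 adjusted over the list alone (camera adjusted p = 0.00806; adjusted p = 0.103 with an estimated correlation). Beside WRKY53 this was WRKY47 at 1.02 ± 0.30. WRKY53 and WRKY22 belong to both the immunity and the WRKY list, so these are not independent.

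In the jasmonate and ethylene list, 2 of 3 measured members rose adjusted over the list alone and 0 over all probe sets. These were the plant defensin genes PDF1.2b at 1.49 ± 0.29 and PDF1.2 at 0.81 ± 0.19, and the PDF1.2b probe set is of a kind that can also bind related transcripts. The list as a whole, with 3 of 30 listed genes measured, did not pass (camera adjusted p = 0.0513, or 0.166 with an estimated correlation). Whether it passed turned with the setting. With a preset correlation camera adjusted p ran from 0.00142, with a trend and robust prior, to 0.122, without wild-type replicate 3.

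Genes of photosynthesis stood lower as a group, though only 6 of the 38 listed genes were measured. All 6 measured members had lower estimates, with a median of −0.81, and 5 fell adjusted over the list alone against 0 over all probe sets (camera adjusted p = 3.91e-05; adjusted p = 0.0726 with an estimated correlation). LHCB4.2 and LHCB4.1, which encode the minor antenna protein CP29, fell 2.96-fold and 2.09-fold. PSAE-1, a photosystem I subunit, fell 1.72-fold, and RCA, which encodes Rubisco activase, fell 1.80-fold, from 32002 ± 1193 to 17939 ± 3219. Of 26 genes listed for abscisic acid, cold and drought, 4 were measured. All 4 also had lower estimates, with a median of −0.52 (camera adjusted p = 0.00208, or 0.0914 with an estimated correlation). Of these, 2 fell adjusted over the list alone and 0 over all probe sets. They were the cold-regulated genes COR15A at −1.76 ± 0.29 and COR47 at −0.59 ± 0.17.

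The low-oxygen list had 2 measured members and did not pass (camera adjusted p = 0.249). With members taken by locus alone, chosen after the list results were seen, it had 6 and passed (adjusted p = 0.00703; adjusted p = 0.115 with an estimated correlation). AT3G10040, which encodes a trihelix factor of the low-oxygen response, stood at 2.06 ± 0.79 (adjusted p = 0.332) and PDC2, a pyruvate decarboxylase gene, at 0.03 ± 0.20. The oxidative stress list did not pass either (camera adjusted p = 0.249), with the zinc finger gene STZ at 1.03 ± 0.38 and GSTU25 at 0.02 ± 0.18. The flavonoid list gave an adjusted p of 0.178, and 0.018 by locus alone (0.115 with an estimated correlation), with DFR at −0.53 ± 0.26 and UGT78D2 at −0.57 ± 0.36. Root-preferential genes, a check on the makeup of the seedling samples, gave 0.0931, with the root hair expansin genes EXPA7 at −0.86 ± 0.35 and EXPA18 at −0.62 ± 0.30. The cell cycle list gave 0.619, with AUR1 at −0.38 ± 0.28 and AUR2 at 0.06 ± 0.22. Heat shock and circadian lists had 1 measured member each and no list test. ATHSP22.0 stood at 0.26 ± 0.43, and the clock gene GI at −0.76 ± 0.21, with a p of 0.0103 over its list of 1 and 0.198 adjusted over all probe sets.

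**Figure D2:**
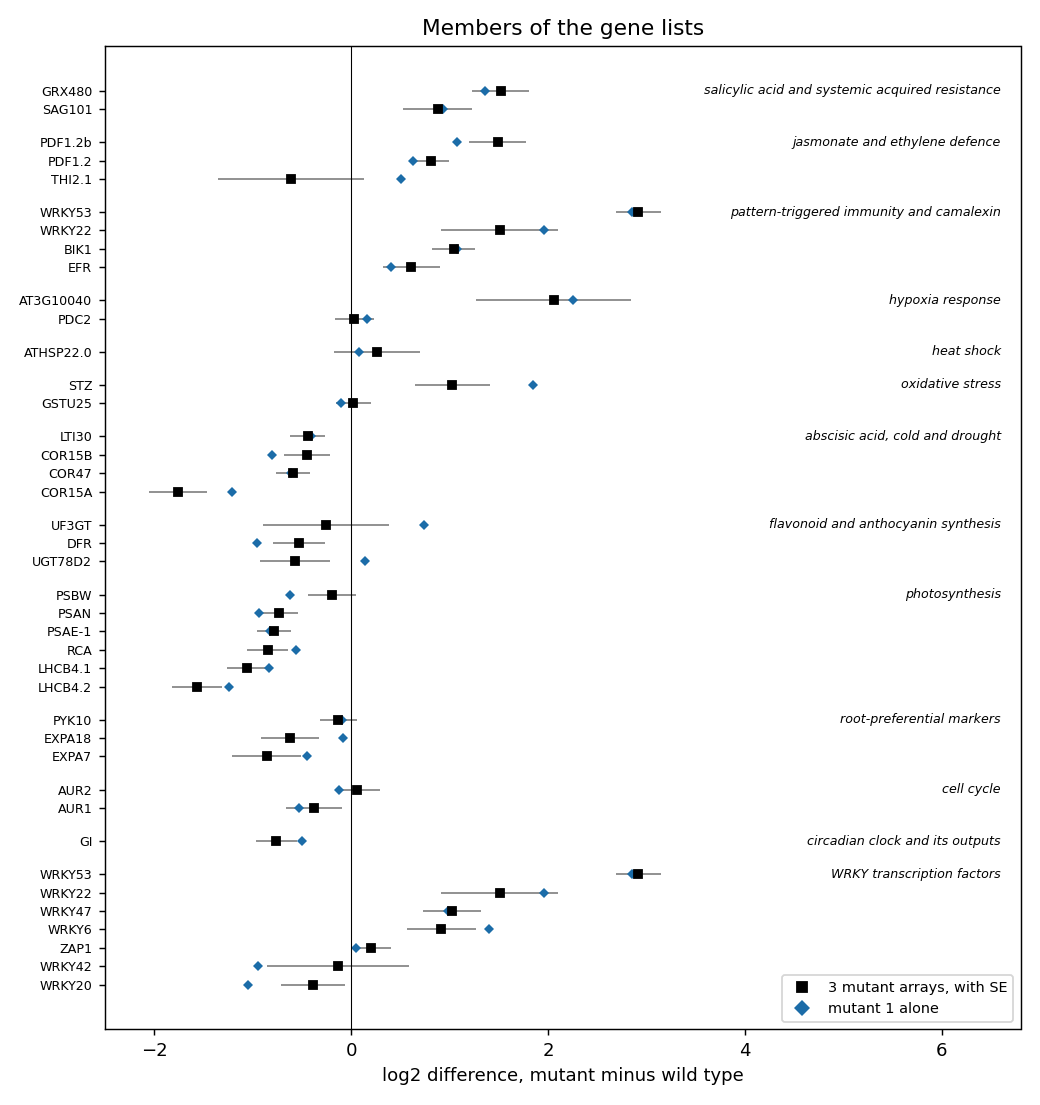
Log2 difference of mutant minus wild type for each measured member of each gene list; black squares with bars are estimates with SE from 3 arrays per genotype, and blue diamonds are mutant replicate 1 minus the wild-type mean. Members of the photosynthesis list all lie below 0, and those of the pattern-triggered immunity list all lie above 0.

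Mutant replicates 2 and 3 stood apart in the control probe sets, and every gene group above was measured on them. The ratio of 3′ to 5′ signal of actin was 28.9 and 19.6 on these arrays, against 2.17 to 2.66 in the wild type and 2.13 in mutant replicate 1. For GAPDH it was 1.75 and 1.70 against 0.794 to 0.844, with 0.996 in mutant replicate 1. On mutant replicate 1 alone, which had a part in the choice of these genes, WRKY53 stood 2.86 above the wild-type mean on the log2 scale, PRX52 4.43, NRT2.5 3.58 and AT5G40140 −2.19. The median over list members on that array was 1.52 for pattern-triggered immunity, 1.15 for salicylic acid, 0.99 for WRKY factors, 0.63 for jasmonate and ethylene, −0.83 for photosynthesis and −0.71 for abscisic acid, cold and drought. For flavonoid genes it was 0.14, against −0.53 over all arrays, and for root-preferential genes −0.10, against −0.62. Tested alone against the wild type, mutant replicate 1 gave 0 calls by limma, with 2194 probe sets at an unadjusted p under 0.05, and the salicylic acid and WRKY lists no longer passed (adjusted p = 0.0779 and 0.155).

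**Figure D3:**
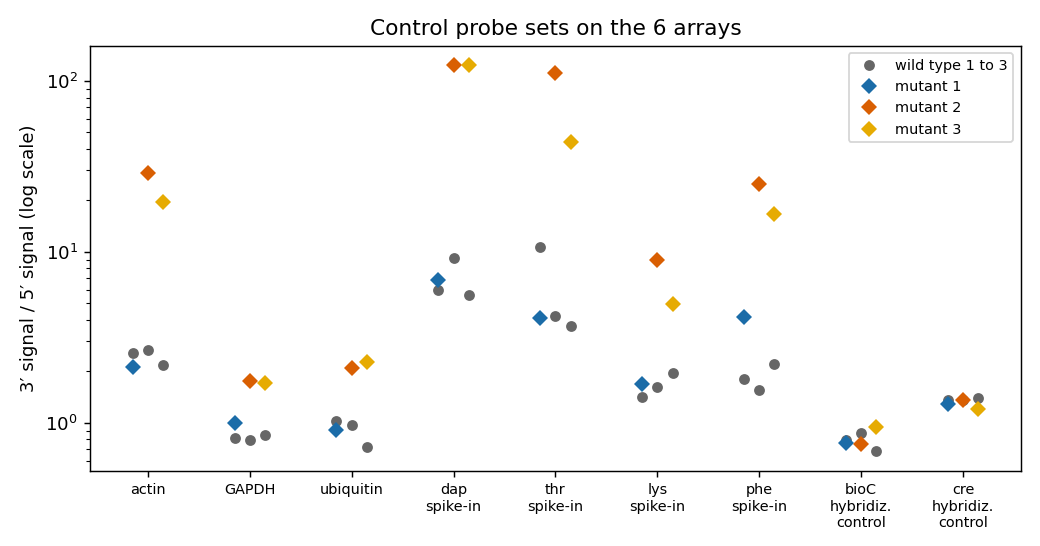
Ratio of 3′ to 5′ signal (log axis) of 9 control transcripts on the 6 arrays; grey circles are wild-type arrays and diamonds mutant arrays. Mutant replicates 2 and 3 lie above all other arrays for the plant and spike-in controls, up to 123.6 for dap, and not for the cre hybridization control.

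Without any one of wild-type replicates 1, 2 and 3 or mutant replicates 2 and 3 limma called 0 probe sets, with 2443 to 2594 at an unadjusted p under 0.05, and without mutant replicate 1 it called 314, 156 higher and 158 lower. The count also depended on the variance model, since an intensity trend with a robust prior called 1459, 813 higher and 646 lower, that is 55.7% higher against 77.5%, and these held 132 of the 162 higher and 18 of the 47 lower calls.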

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

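All tests in this part were chosen after the results were seen. Control probe sets took no part in the comparison, and several stood on mutant arrays far above the wild-type range. The 3′ to 5′ ratio of actin was 28.9 in mutant replicate 2 and 19.6 in mutant replicate 3, that of GAPDH 1.75 and 1.70, and that of ubiquitin 2.1 and 2.27. Among the spike-ins the ratio was 123.6 and 123.5 for dap, 111 and 44.1 for thr, 9.01 and 4.95 for lys, and 24.8 and 16.7 for phe. For phe it was also raised in mutant replicate 1, at 4.13, against 1.56 to 2.21 in the wild type. The 5S ribosomal RNA probe set read 238, 535 and 352 in mutant replicates 1, 2 and 3, against 76.9 to 100.3 in the wild type.

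The pattern of lost 5′ signal in mutant replicates 2 and 3 was weighed against 3 explanations. The mean log2 ratio of the 4 spike-ins was 3.29 higher on these arrays than on the other 4, whose SD was 0.14, while hybridization controls, which enter after labelling, moved by 0.02. Breakdown of the plant RNA alone would leave the spike-ins in place, but even the lower of both spike-in means lay 2.79 above the highest of the other arrays. Shorter labelled cRNA on these arrays is a candidate explanation. An effect of the genotype on plant transcripts alone would also leave the spike-ins in place, so their shift of 3.29 argues against it. An effect of the genotype that also reached the spike-ins was not tested. In the plant controls mutant replicate 1 differed from the wild type by 0.0329, but it is 1 array. Replicates 2 and 3 stood 1.87 above the other arrays there.

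The 156 probe sets called higher without mutant replicate 1 may owe their calls to the same loss of signal, or to the genotype. When the top 250 higher probe sets were chosen on mutant replicates 2 and 3 against a pair of wild-type arrays, mutant replicate 1 lay above the held-out wild-type array in 75.6% to 78.8% of them, with a median difference of 1.32 to 1.42 on the log2 scale, where arrays that do not differ would give 50%. Mutant replicates 2 and 3, held out in the same way, gave 76.8% to 78.8% and 1.48 to 1.59. These values go against lost 5′ signal as the whole cause of such rises. A single array cannot exclude it, and a difference of line or growth that is not AtR8 was not tested.

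For the 158 probe sets called lower without mutant replicate 1 the same reading decided little. Mutant replicate 1 lay below the held-out wild-type array in 63.2% to 67.2% of the top 250 lower probe sets, with a median of −0.24 to −0.26, and replicates 2 and 3, held out in turn, in 53.6% to 63.2%, with a median of −0.08 to −0.41. Weak agreement was thus not particular to mutant replicate 1, and lost 5′ signal stays open for these calls. The linear share of the difference seen in the held-out arrays was larger for higher than for lower probe sets by 0.412 to 0.449 in mutant replicate 1, but by 0.52 to 0.706 in replicates 2 and 3, so wild-type material mixed into mutant replicate 1 was not excluded either. Of the 47 lower calls over all arrays, 35 lie among the dimmest 30% of probe sets, as do 36 of the 162 higher calls. Brightness was the mean over all arrays, so a fall itself lowers it.

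The 6 arrays make 10 splits into equal groups, too few for a share under 0.05. In 1 of the 10 splits, the real one, there were as many calls: 209 changed, 209 changed at least 2-fold, 162 higher and 47 lower, and the highest of the other splits gave 0 for each. The real camera p and the smallest of the other splits were 0.00592 and 0.0631 for salicylic acid, 2.88e-05 and 0.0359 for pattern-triggered immunity, 0.000568 and 0.13 for abscisic acid, cold and drought, 3.55e-06 and 0.0819 for photosynthesis, and 0.00293 and 0.0887 for WRKY factors.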

How the results depend on the processing

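The limma counts moved with most settings. The cause of each change was not tested unless it is named. Quantile normalization and median centring gave 209 calls again, but the deposited values were already quantile normalized, so these could move almost nothing. Chosen after the data were seen, cyclic loess gave 214, with 159 of the 162 higher and 44 of the 47 lower calls shared. No setting moved the median of all probe sets by 0.1 on the log2 scale.

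Changed, higher, lower and at least 2-fold counts were, in this order, 359, 282, 77 and 329 without the dimmest 30 percent of probe sets, where fewer probe sets were tested and 126 higher and 12 lower calls were shared. They were 1459, 813, 646 and 675 with a trend and robust prior, where only 132 of the 162 higher and 18 of the 47 lower calls were shared. With a pseudocount of 1 they were 99, 78, 21 and 99, with 77 higher and 20 lower calls shared, and with a pseudocount of 64 they were 336, 269, 67 and 323, with 145 and 32 shared. Array weights gave 305, 229 higher and 76 lower, and shared all 162 and 47. The lowest weight, 0.511, went to mutant replicate 1, while mutant replicates 2 and 3, with lost 5′ signal, had 1.05 and 1.33. This setting is therefore no correction for the lost 5′ signal. Leaving out each array in turn gave 0 to 314 changed, 0 to 156 higher, 0 to 158 lower and 0 to 314 at least 2-fold, with fewer samples in each fit. Only the fit without mutant replicate 1 called any, and it shared 108 higher and 27 lower calls with all arrays.

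With the replicate number as a block limma called 0 in every one of these counts (2769 at an unadjusted p under 0.05). Same-numbered arrays deviated with correlations of 0.0141, 0.0115 and 0.00455, which shows no pairing across all probe sets. A pairing limited to some genes was not excluded. A term for mutant replicates 2 and 3 gave 0 for all 4 counts (2291 unadjusted), and mutant replicate 1 alone gave 0 (2194 unadjusted). Both leave the mutant with 1 informative array, which is assumed to vary like the others.

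With an estimated correlation, which also brings fewer degrees of freedom, the adjusted p of all 5 lists past the threshold rose above it: 0.111 for salicylic acid, 0.0726 for pattern-triggered immunity, 0.0914 for abscisic acid, cold and drought, 0.0726 for photosynthesis and 0.103 for WRKY factors. Salicylic acid was also past it no longer without mutant replicate 1 (0.0559), with the term for mutant replicates 2 and 3 (0.0519) and with mutant replicate 1 alone (0.0779). WRKY factors were at 0.0902 and 0.155 in the latter pair. Jasmonate and ethylene passed without the dimmest probe sets (0.00537), with trend and robust prior (0.00142), with a pseudocount of 64 (0.0297), without mutant replicate 2 (0.0343) and with members by locus alone (0.042). The last setting, added after the list results were seen, also brought the low-oxygen list, with 4 more members, to 0.00703 and the flavonoid list, with 2 more, to 0.018. The jasmonate and ethylene list kept its members there, and its adjusted p fell because these lists moved ahead of it in the adjustment. Averaging all probe sets of a gene changed the side of no list.

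Leaving out each array in turn, adjusted p ranged from 0.00585 to 0.0559 for salicylic acid and from 0.0343 to 0.122 for jasmonate and ethylene, and no other list changed sides.

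The 25 genes named in the main results and past the threshold all stayed past it with quantile normalization, median centring, array weights and cyclic loess, 23 with a pseudocount of 64 and with averaged probe sets, 20 without mutant replicate 1, 16 with a pseudocount of 1 and 15 with trend and robust prior. The 10 lost with trend and robust prior were all among the 12 largest falls. Without the dimmest probe sets 11 were tested and all 11 stayed, but 0 of the 12 largest falls were among them. In the settings with 0 calls none did. Up to 13 other named genes passed in a single setting, the most with trend and robust prior.

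Genes that reversed were all far from the threshold. Leaving out each array in turn gave −0.0552 to 0.203 for AUR2, −0.182 to 0.545 for ATHSP22.0, −0.0341 to 0.14 for PDC2 and −0.0262 to 0.0868 for GSTU25 on the log2 scale. AUR2 gave −0.12 with the term and with mutant replicate 1 alone, GSTU25 −0.11 and UGT78D2 0.14 in both.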

Other observations

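All tests in this part, and the genes named in it, were chosen after the table of all probe sets was seen. The berberine bridge enzyme-like family held 6 of the 83 higher calls with a single named gene, among 22 measured genes, and 0 lower calls. AT1G26380 rose by 2.89 ± 0.23 on the log2 scale, AT1G26420 by 2.78 ± 0.23, AT1G30700 by 2.32 ± 0.25 and AT4G20860 by 2.18 ± 0.26, beside AT1G26390 and AT1G26410. The family was picked because of these calls, so its camera p of 8.73e-08 (p = 0.0353 with an estimated correlation) is no independent evidence that it is raised as a whole. The other members had a median of 0.36, and on mutant replicate 1 alone the family's median was 0.06 (p = 0.101 with an estimated correlation).

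Loci known to respond to low oxygen were looked at again because the fixed list had kept only 2 measured members. Taking the fixed list by locus alone gave 6 members, of which AT1G33055 rose 4.34-fold (adjusted p = 0.0324), and the list passed with a preset correlation (adjusted p = 0.00703) and not with an estimated one (adjusted p = 0.115). A larger list was written from memory after the calls were seen. It had 22 measured loci, 18 of them with higher estimates and 3 higher calls, AT1G33055, AT1G72940 and CML38. It left out PDC2, which stood at 0.03 ± 0.20. It repeated AT1G33055, AT3G10040, AT4G17260, AT4G27450 and AT5G10040, so it was not independent of the fixed list taken by locus. Its median was 0.46, with a camera p of 7.84e-06 and a p of 0.00819 with an estimated correlation, and mutant replicate 1 alone gave a median of 0.56 (p = 0.0379 with an estimated correlation). One hypothesis is that low-oxygen genes may return to baseline later in the mutant, but a list written after the calls cannot support it, and seedlings without the stress were not analysed here.

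Gene families were formed from symbol stems under 2 definitions, 1 tried after the other, with 127 and 52 families. Calmodulin-like genes (CML) ranked first in both with a preset correlation, with higher estimates in 7 of 8 genes but 1 higher call, a median of 1.02, and adjusted p-values of 0.00341 and 0.0014. With an estimated correlation these were 0.83 and 0.488, so a shift of the whole family was not shown. In the second definition, peroxidase genes with a PRX symbol had higher estimates in 5 of 5 genes, 3 higher calls and a median of 1.55. Of the 5, AT5G66390 stood at only 0.006 and AT2G41480 at 0.12. CRR genes had lower estimates in all 7 genes, 0 calls and a median of −0.56. With an estimated correlation, camera gave PRX and CRR smaller unadjusted p-values (0.016 and 0.025) than CML (0.0325). All 3 families had the same camera adjusted p of 0.488 there. CML38, known as a calcium sensor of the low-oxygen response, rose 4.30-fold (adjusted p = 0.0432).

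Higher-called genes lay next to each other in gene order in 4 pairs, against 0.495 expected from 10000 permutations of the calls over 13264 nuclear genes (p = 0.001). The pairs were AT1G26380 with AT1G26390, AT1G26410 with AT1G26420, YLS5 with AT2G38870, and AT5G52750 with AT5G52760. Of these, 2 pairs belong to the berberine bridge enzyme-like family, whose calls prompted the test. Without that family 2 pairs remained, against 0.433 expected from 10000 permutations (permutation test, p = 0.068), so a random scatter of the other calls was not excluded. Of the 8 probe sets in these pairs, 0 carry a suffix that marks probes shared with other transcripts, but cross-hybridization itself was not measured.

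Chloroplast-encoded genes, with 69 named probe sets, had a median log2 difference of 0.04 and 2 changed probe sets. The 25S ribosomal RNA probe set read 1105 in mutant replicate 1 and 143 and 121 in mutant replicates 2 and 3, against 583 to 1061 in the wild type.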
